A study of Mus musculus with 16 samples.

How the data were processed

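Messenger and other long RNA of mouse liver was measured by sequencing in 16 libraries. They fall into 4 groups by the diet and genotype in the labels. Each library entered the group its own labels give, and replicate numbers within a group follow accession order and pair nothing. Per the labels' protocols, livers were snap frozen, total RNA was depleted of ribosomal RNA with a Ribo-Zero kit, and reads were quality trimmed, aligned with TopHat2 and quantified with Cuffdiff. The genome build was mm10, per the submitters' processing notes. Versions of these tools are not given in the sources used here. Per the labels' protocols, a small RNA library kit and 45 cycles were used but reads are given as 75 bases long, and these statements were not reconciled here. The strand setting of the counting is not given in the sources used here.

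The deposited table holds 1 row per gene, with 23258 rows, and 1 column of estimated counts per library. Its name speaks of FPKM, but its values were neither scaled to library size nor to gene length: between 32.8% and 37.9% of the values of a library were exactly whole (tolerance 0), and the library totals differed. How the authors made these estimated counts is not stated in the labels. The source of the fractions was not tested. Values of near-identical copies, of overlapping genes and of antisense genes are uncertain, since the counting could split reads between them. The smallest row total was 10, so rows with lower totals were absent from the table. Of the largest values, 24 were at least 1000000 and carried at most 3 significant digits. Spreadsheet conversion had turned 22 gene names into dates, and 20 of these were recovered from their coordinates. Of the names, 22315 were found in GENCODE M21, and 20935 of those had the same chromosome, strand and limits.

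Estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the 4 groups, which left 16830. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation was fitted to all 16 libraries with a mean per group and 12 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested within a comparison and a threshold of 0.05. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. Counts scaled to library size (CPM) use TMM-scaled totals and are given as mean ± SD. Log2 CPM used a prior count of 2. The 6 comparisons were knockout against wild type on each diet, their mean, their difference, and high-fat diet against chow in each genotype.

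Gene lists, 32 in all, were written from general knowledge of liver biology before the data were examined. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 32 lists. Named genes followed a rule set before the data were examined. For each comparison it took Srebf2, the 8 largest rises and 8 largest falls among genes that passed, had a mean of at least 1 CPM in the higher group and did not overlap between groups, and up to 3 members of each list that passed or 1 that did not. For the difference and the mean it took 5 each way, and where fewer than 5 genes passed it took the 5 with the smallest p. Unnamed gene models were left out. Predicted miR-33-5p targets were genes whose longest annotated 3' UTR of at least 20 bases held a seed site, compared with 10000 random sets matched on UTR length and expression. Where every library of a group had a count of 0, a lower bound was computed from 3 counts in each of its libraries, which covers counting error only. For medians of lists, a log2 bound under 0 was set to 0, since both groups then lay under that floor.

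The edgeR fit was tested on simulated counts for the 16830 genes, camera on simulated counts for 1 comparison and the comparison of site genes on simulated values, while the exact tests, the ranking of 7-mers and the relations across genes were not simulated in this way. In each simulated comparison 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, and genes were drawn independently. For knockout against wild type on high-fat diet, 67.2% of genes changed 2-fold and 41.8% of genes changed 1.5-fold were recovered. For knockout against wild type on chow the shares were 52.2% and 26.9%. For the difference between diets they were 38.8% and 10.4%. No recovered gene had the wrong sign, and 7, 3 and 5 unchanged genes were also called in these comparisons. More genes were changed in the simulations than passed in these real comparisons, which loosens the adjusted threshold. The shares may therefore overstate recovery in the real comparisons. For knockout against wild type on high-fat diet, camera at the preset correlation called the 1 raised list and 1 of the others. For site genes among 13118, an added shift of 0.2 was estimated as 0.198 and no shift as -0.0025.

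Totals ran from 15888436 to 29469645 estimated counts per library. Alternatives set before the data were examined were size factors of DESeq2 1.42.0, no filter, a filter of 5 CPM in at least 3 libraries, the DESeq2 Wald test, voom with quality weights, a fit of only the groups compared, and leaving out each library in turn. A ribosomal RNA covariate and a fit without the pair of libraries that stood apart were added after the data were seen. All replicate pairs differed by more than sampling noise (chi-square per degree of freedom of at least 13.3). Calculations used R 4.3.3 and Python 3.11.15.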

Results

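Liver RNA was sequenced from C57BL/6 mice that were wild type or carried a liver-specific knockout of miR-33, a microRNA known to repress the cholesterol exporter Abca1. Wild-type livers numbered 3 on chow and 4 on high-fat diet, and knockout livers numbered 4 on chow and 5 on high-fat diet. Library totals were 17502937 to 22902669 estimated counts in wild type on chow, 15888436 to 26821573 in knockout on chow, 16149911 to 25823475 in wild type on high-fat diet and 20993930 to 29469645 in knockout on high-fat diet. The labels do not state that the libraries came from separate animals or give batch, sex or age, so p-values measure only the spread between these libraries. The numbers in the titles, which may be animal numbers but are not labelled so, form different series on each diet. Diet and number series therefore cannot be told apart. On the first principal component, chow libraries lay between -58.1 and -44.5 and high-fat libraries between 15.3 and 54.3. The ribosomal RNA gene CT010467.1 took 0.637% to 14.6% of the counts of a library. High-fat knockout 1 stood apart on the third component at -50.2, and chow wild type 3 on the second at -48.8.

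The microRNA itself was not analysed here, so no value checks the deletion or shows which cell types of the liver carry it. The deposited name of the counts includes Alb-Cre, but no value here tests where this driver acted. Its host gene Srebf2, which encodes a regulator of cholesterol synthesis, had 53.4 to 65.4 CPM in wild type on chow, 47.3 to 59.1 in knockout on chow, 45.0 to 51.1 in wild type on high-fat diet and 40.7 to 59.9 in knockout on high-fat diet. Srebf2 spans 82147266 to 82205376 on chromosome 15 of mm10. Its knockout log2 fold changes were 0.04 ± 0.11 (SE) on high-fat diet and -0.11 ± 0.12 on chow, within the spread between libraries (edgeR adjusted p = 1.00 and 0.94).

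On high-fat diet, the question was which genes differ in livers labelled as miR-33 knockout. The histone H2B gene Hist1h2br, on chromosome 13 at 21833743 to 21837530, rose in knockout livers from 0.370 ± 0.184 CPM (SD, n = 4) to 3.47 ± 0.582 CPM (n = 5). Its log2 fold change was 3.18 ± 0.33, with an edgeR adjusted p of 2.5e-04. It was the 1 gene of 16830 that passed, while 641 (3.81%) had an unadjusted p under 0.05 and the DESeq2 Wald test called 8. Abca1 had 335 ± 34.4 CPM in knockout and 269 ± 8.86 CPM in wild type, a log2 fold change of 0.32 ± 0.08 that did not pass over all genes (adjusted p = 0.92). Adjusted over the list alone, 1 of the 29 miR-33 targets from the literature passed, which was Abca1, against 0 over all genes. Of this list 24 of 29 lay above 0, with a median of 0.06, and the camera adjusted p was 0.0674 at the preset correlation (adjusted p = 0.304 with an estimated correlation).

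**Figure D1:**
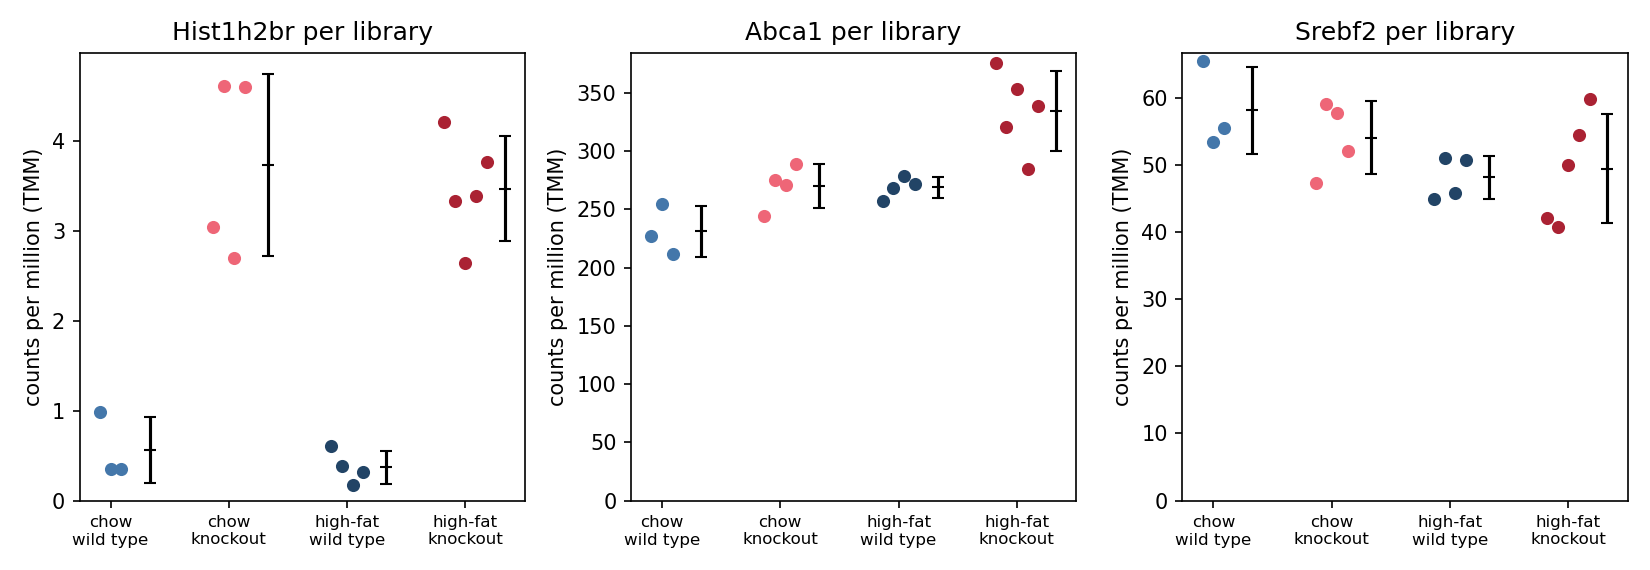
CPM (library-size-scaled counts) of Hist1h2br, Abca1 and Srebf2 in each library (points), by group on the horizontal axis, with the group mean and SD as a bar beside the points. Hist1h2br lay between 2.64 and 4.61 CPM in the knockout libraries and between 0.168 and 0.988 CPM in the wild-type libraries.

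Among the gene lists on high-fat diet, sinusoidal endothelial markers had a median knockout log2 fold change of -0.34 and 12 of 15 members below 0. None of them passed over all genes, and 8 passed adjusted over the list alone. The camera adjusted p was 1.6e-11 at the preset correlation, and the adjusted p = 0.166 with an estimated correlation. The endothelial adhesion gene Selp had 1.78 ± 0.408 CPM in knockout and 3.94 ± 0.595 in wild type (log2 -1.15 ± 0.19, adjusted p = 0.059). Pecam1, another endothelial adhesion gene, had a log2 fold change of -0.66 ± 0.18. Markers of other cell types lay on both sides of 0. Neutrophil markers had a median of -1.02 and 6 of 6 below 0, with 0 passing over all genes and 1 adjusted over the list alone (adjusted p = 0.166 with an estimated correlation). Erythroid and cholangiocyte markers had medians of -0.60 (8 of 8 below 0) and -0.36 (8 of 10), with 0 passing by either adjustment (adjusted p = 0.342 and 0.307 with an estimated correlation). Kupffer cell markers had a median of -0.16 and 13 of 16 below 0, with 0 passing over all genes and 1 adjusted over the list alone, and stellate cell markers had -0.16 and 11 of 15, with 0 by either (adjusted p = 0.573 and 0.503 with an estimated correlation). B and plasma cell markers lay above 0 in 10 of 10, with a median of 0.57, which was -0.03 without high-fat knockout 1, and 0 passed by either adjustment (adjusted p = 0.503 with an estimated correlation). T and NK cell markers lay above 0 in 10 of 14 (median 0.22), hepatocyte markers in 12 of 16 (0.04) and adipocyte markers in 4 of 6 (0.16), with 0 passing by either adjustment (adjusted p = 0.794, 0.794 and 0.918 with an estimated correlation). The adipocyte mean was -0.02, opposite in sign to its median. Some of these medians moved by over 1.5 times with 1 library left out. The Kupffer cell median was -0.28 and 0.03 without high-fat wild type 1 and 2, and -0.38 and -0.07 without high-fat knockout 1 and 2. The cholangiocyte median was -0.64 and -0.05 without high-fat wild type 1 and 2, and the erythroid median -0.33 without high-fat wild type 2 and -1.02 without high-fat knockout 4. The stellate cell median was -0.24 and -0.10 without high-fat wild type 1 and 4 and -0.10 without high-fat knockout 2, and the neutrophil median -0.62 without high-fat knockout 3. Fibrosis and matrix genes had a median of -0.34 over 34 members, with 0 passing by either adjustment, and an adjusted p = 0.182 with an estimated correlation, and the median was -0.21 without high-fat wild type 4. Cholesterol synthesis genes had a positive value in 26 of 27 members and a median of 0.16, with 0 passing by either adjustment (adjusted p = 0.609 with an estimated correlation). That median was 0.29, 0.31, 0.09 and 0.06 without high-fat knockout 1, 2, 3 and 5. At the preset correlation 14 of the 32 lists passed, and 0 did with an estimated correlation. Selp passed with no filter, in the DESeq2 Wald test and with voom, at adjusted p values of 0.046, 9.6e-05 and 0.016.

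On chow, Hist1h2br was again higher in knockout livers, at 3.73 ± 1.01 CPM (n = 4) against 0.564 ± 0.367 (n = 3). The log2 fold change was 2.68 ± 0.37 (edgeR adjusted p = 0.016). It was the 1 gene that passed, while 1001 (5.95%) had an unadjusted p under 0.05 and the DESeq2 Wald test called 2. The call was lost without chow wild type 2, chow wild type 3 or chow knockout 2, at adjusted p values of 0.142, 0.0944 and 0.0873. It was also lost with voom (0.185), in a fit of only those groups (0.302) and without high-fat knockout 1 and chow wild type 3 (0.115), while the log2 fold change stayed between 2.43 and 2.71 in these fits. The stricter filter left the gene out. The count of genes was 0 without chow wild type 2 or chow knockout 2, 2 without chow wild type 1 or 3, and 3 without chow knockout 4. Abca1 had 270 ± 18.5 CPM in knockout and 231 ± 21.8 in wild type (log2 0.22 ± 0.09, adjusted p = 0.81). Of the 29 literature targets 20 lay above 0, with a median of 0.06 and 0 passing by either adjustment, over all genes or adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). Mvk, which encodes mevalonate kinase of the cholesterol pathway, had a log2 fold change of -1.17 ± 0.28 (adjusted p = 0.76).

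On chow, the endothelial list pointed the other way, with 15 of 15 members above 0 and a median of 0.35. Of its members 0 passed over all genes and 8 adjusted over the list alone, and the list had an adjusted p = 0.316 with an estimated correlation. Stab2, a scavenger receptor of sinusoidal endothelium, had 49.1 ± 6.48 CPM in knockout and 35.4 ± 2.88 in wild type (log2 0.47 ± 0.15, adjusted p = 0.77). Cholesterol synthesis genes were below 0 in 27 of 27 members, with a median of -0.27, 0 passing over all genes and 1 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). Kupffer cell and macrophage markers were above 0 in 16 of 16, with a median of 0.61 and 0 passing by either adjustment (adjusted p = 0.575 with an estimated correlation). Neutrophil markers had a median of 1.59, which was 0.98 with the log2 fold change of Mmp8 set to 0. Mmp8 had 0 counts in chow wild type and a bound under 0. T and NK cell markers had a median of 0.83. Of these lists 0 members passed by either adjustment (adjusted p = 0.575 for both with an estimated correlation). Stellate cell, B and plasma cell and erythroid markers had medians of 0.15, 0.52 and 0.01, and cholangiocyte, hepatocyte and adipocyte markers had -0.07, -0.01 and -0.21, with 0 passing by either adjustment (adjusted p = 0.753, 0.753, 0.925, 0.788, 0.925 and 0.753 in that order with an estimated correlation). The adipocyte mean was 0.32, opposite in sign to its median. The Kupffer cell median was 1.03 and 0.39 without chow wild type 1 and 2, the T and NK cell median 1.31 without chow wild type 1, the neutrophil median 1.04 and 0.41 without chow knockout 1 and 4, and the stellate cell median 0.04 and 0.23 without chow knockout 2 and 3. At the preset correlation 13 lists passed, and 0 with an estimated correlation. The count of 13 was 6 without chow wild type 3, and 5 without high-fat knockout 1 and chow wild type 3.

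The mean of both diets asked for knockout effects shared by them. Hist1h2br (log2 2.93 ± 0.25, adjusted p = 1.0e-05), Hist1h2bq (3.68 ± 0.50, 0.0070) and Hist1h2bk (2.85 ± 0.40, 0.0072) rose, and 586 genes (3.48%) had an unadjusted p under 0.05. These 3 histone H2B genes lie on chromosome 13, Hist1h2bq at 21806612 to 21810197 and Hist1h2bk at 22035870 to 22036345. Hist1h2bq had 1.26 ± 0.306 CPM in knockout and 0.0969 ± 0.0704 in wild type on high-fat diet, so wild-type values rest on few counts. H2B genes are near-identical in sequence, and how reads were divided between them is uncertain. The call of Hist1h2bk was lost without chow wild type 1 (log2 2.69, adjusted p = 0.0663) and without high-fat knockout 1 and chow wild type 3 (2.76, 0.0722). With voom the adjusted p was 0.406 for Hist1h2bq (log2 3.68) and 0.234 for Hist1h2bk (2.73). Without chow wild type 3 the count of genes was 5. Next among named genes by p was Hfe (log2 -0.25 ± 0.05, adjusted p = 0.55), and Abca1 had 0.27 ± 0.06 (adjusted p = 0.95). Of the 29 literature targets 19 lay above 0, with a median of 0.04, which was 0.09 without chow wild type 2, and 0 passed over all genes and 1 adjusted over the list alone, again Abca1. The list passed at the preset correlation (camera adjusted p = 0.0300) and not with an estimated one (adjusted p = 0.328 with an estimated correlation). Its preset call was also lost without chow wild type 1 or 3, chow knockout 3, high-fat wild type 1 or 2 or high-fat knockout 3. Xenobiotic and NRF2 genes had the smallest camera p at the preset correlation. They lay above 0 in 22 of 24, with a median of 0.17 and 0 passing by either adjustment. Their camera adjusted p was 4.5e-04 at the preset correlation and 0.78 with an estimated one. The preset call was lost without chow wild type 2, at a median of 0.11.

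The difference between the knockout effects on the diets was tested for each gene. With edgeR 0 genes passed, while 1110 (6.60%) had an unadjusted p under 0.05, the DESeq2 Wald test called 13 and voom called 0. Without chow wild type 1 edgeR called 4, and without high-fat knockout 1 it called 1. Cd93, an endothelial and myeloid surface receptor, had the smallest p, with a difference of -0.93 ± 0.19 (adjusted p = 0.42). Stab2 had a difference of -0.91 ± 0.20 and Cd14, a lipopolysaccharide co-receptor of macrophages, of -1.26 ± 0.30. In the DESeq2 Wald test the adjusted p was 0.0233 for Cd93, 0.0448 for Stab2 and 0.0484 for Cd14, and without chow wild type 1 it was 0.0472 for Cd14 in edgeR. Endothelial markers had a median difference of -0.67 and were below 0 in 15 of 15, with 0 passing over all genes and 11 adjusted over the list alone (adjusted p = 0.0538 with an estimated correlation). Across genes, which are not independent replicates, the knockout effects on the diets had r = -0.06 and rho = -0.13, and r was -0.168 under the stricter filter. On the log CPM scale r was -0.0885, with an exact two-sided p of 0.145 over 4410 reassignments of genotype within diet.

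**Figure D2:**
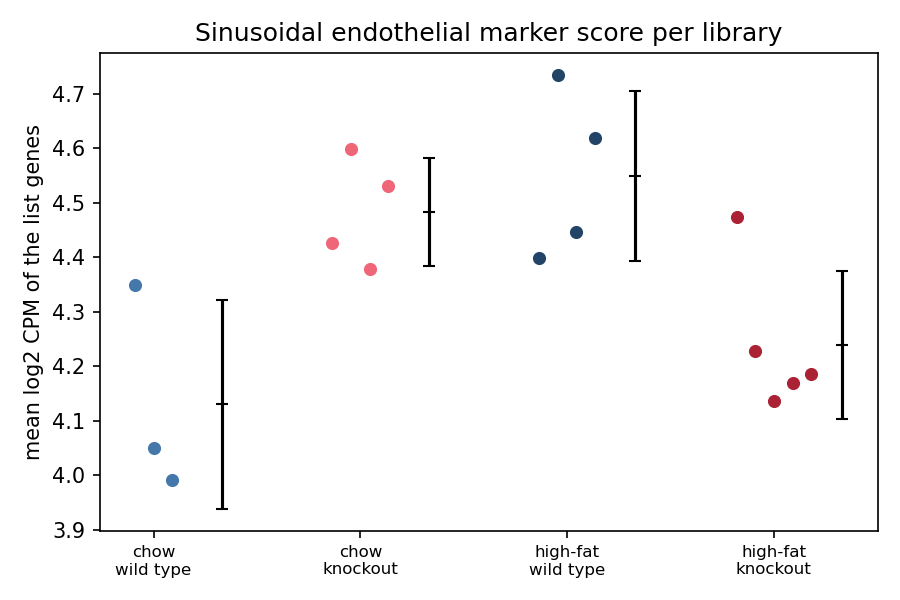
Mean log2 CPM of the 15 sinusoidal endothelial markers in each library (points), by group on the horizontal axis, with the group mean and SD beside them. The knockout mean lay 0.31 below wild type on high-fat diet and 0.35 above it on chow.

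Genes with predicted miR-33-5p sites were compared with matched genes without a site. Among 2066 genes with any site, the mean knockout log2 fold change on high-fat diet differed from that of matched genes by -0.003, with a 95% range of -0.013 to 0.007. On chow the difference was 0.007 (-0.007 to 0.021). Both ranges come from redrawing the matched genes only, and leave out the spread between site genes and between libraries. The per-library difference between genotypes had an exact p of 0.667 on high-fat diet and 0.371 on chow.

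High-fat diet against chow in wild type gave the larger changes. The matrix-degrading enzyme Mmp12 rose from 0.243 ± 0.116 CPM (n = 3) to 16.3 ± 2.44 CPM (n = 4), a log2 fold change of 5.98 ± 0.27 (edgeR adjusted p = 1.6e-10). Sprr1a, a gene of the cornified envelope, had 0 counts in every chow wild-type library and was at least 59.1-fold higher on high-fat diet at 9.71 ± 1.58 CPM. The cytochrome P450 gene Cyp2b13 rose from 0.114 ± 0.159 to 29.8 ± 2.52 CPM. Of 16830 genes, 4946 passed, 2564 higher and 2382 lower. Of these, 1870 changed at least 2-fold, 1460 higher and 410 lower.

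In wild type on high-fat diet, fibrosis and matrix genes rose in 31 of 34 members and fell in 1 by both counts (over all genes and adjusted over the list alone), with a median of 2.04. Col3a1, a fibrillar collagen, rose by 3.57 ± 0.24. Lipid-associated macrophage genes rose in 14 of 16 members over all genes and 15 adjusted over the list alone, with Gpnmb at 5.95 ± 0.47, and Mmp12 belongs to both lists. Inflammatory cytokines and chemokines rose in 16 of 22 over all genes and 17 adjusted over the list alone, including the receptor Tlr2 at 2.69 ± 0.23. These lists kept an adjusted p = 0.0055 with an estimated correlation. Other cell types were also compared. Kupffer cell markers rose in 12 of 16 over all genes and 13 adjusted over the list alone, and stellate cell markers rose in 9 of 15 and fell in 2 by both counts (adjusted p = 0.194 and 0.502 with an estimated correlation). Erythroid markers rose in 7 of 8 by both counts, with 1 falling adjusted over the list alone and a median of 1.57 (adjusted p = 0.494 with an estimated correlation). Neutrophil markers rose in 4 of 6 over all genes, and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.224 with an estimated correlation). Endothelial markers rose in 7 of 15, adipocyte markers in 2 of 6, T and NK cell markers in 2 of 14 and B and plasma cell markers in 0 of 10, each by both counts over all genes and adjusted over the list alone (adjusted p = 0.502, 0.242, 0.645 and 0.645 with an estimated correlation). Cholangiocyte markers rose in 2 of 10 over all genes and 0 adjusted over the list alone (adjusted p = 0.494 with an estimated correlation). Cell cycle genes rose in 19 of 22 by both counts (over all genes and adjusted over the list alone), with the proliferation marker Mki67 at 2.98 ± 0.31, and their median of 1.81 was 1.65 with Bub1, at 0 in chow wild type, at its bound (adjusted p = 0.144 with an estimated correlation).

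Fatty acid oxidation and PPARa targets fell in 23 of 32 by both counts (over all genes and adjusted over the list alone), with Acot1 falling by 2.85 ± 0.21 and the mitochondrial carnitine enzyme Cpt2 by 0.96 ± 0.07. That list had an adjusted p = 0.0714 with an estimated correlation. Lipogenesis genes rose in 14 of 22 over all genes and 15 adjusted over the list alone and fell in 2 by both counts, with Thrsp at 4.08 ± 0.53 (adjusted p = 0.194 with an estimated correlation). Hepatocyte markers fell in 12 of 16 over all genes and 13 adjusted over the list alone, and the transcription factor gene Hnf4a fell by 0.88 ± 0.11 (adjusted p = 0.194 with an estimated correlation). Bile acid genes fell in 10 of 20 and rose in 1 by both counts (over all genes and adjusted over the list alone), with the uptake transporter Slc10a1 falling by 0.99 ± 0.09 and the sterol hydroxylase Cyp8b1 by 1.76 ± 0.25 (adjusted p = 0.2 with an estimated correlation).

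Growth hormone dependent and sex-biased genes fell in 12 of 23 members over all genes and 13 adjusted over the list alone, and 3 rose by both counts (adjusted p = 0.564 with an estimated correlation). Sex is not given in the labels, and whether it differed between the diet groups was not tested. The elongase gene Elovl3 fell from 201 ± 31.8 to 23.4 ± 14.3 CPM. Among the largest falls, the major urinary protein gene Mup14 fell from 750 ± 464 to 24.2 ± 7.22 CPM and the serpin gene Serpina1e from 1852 ± 944 to 64.1 ± 18.4 CPM. Mup and Serpina1 genes are families of near-identical copies, so the division of reads between them is uncertain. Mup14 and Serpina1e lost their call without chow wild type 2, at adjusted p values of 0.0854 and 0.0648, and without any 1 of the high-fat wild-type libraries, at 0.0633 to 0.0818 and 0.0517 to 0.0654. Hsd3b5, a steroid dehydrogenase gene, fell by 8.38 ± 2.59 and lost its call without the same libraries, at adjusted p values of 0.0581 to 0.0833. Mup12 fell by 4.66 ± 1.52 and lost its call without chow wild type 1 or 2 (adjusted p = 0.0521 and 0.106) or high-fat wild type 2, 3 or 4 (0.0827 to 0.0914) and with no filter (0.0504). Mup15 fell by 4.51 ± 1.5 and lost its call without chow wild type 1, 2 or 3 (0.05002, 0.141 and 0.0505) or high-fat wild type 2, 3 or 4 (0.0843 to 0.0976), with no filter (0.0548) and with the ribosomal RNA covariate (0.0523), chosen after seeing the data.

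Other calls in wild type were lost when 1 library was left out, while their sign stayed. The fit without high-fat knockout 1 and chow wild type 3, chosen after seeing the data, is called the fit without both libraries here. The fibrinogen genes Fgg, Fgb and Fga fell by 0.68 ± 0.18, 0.67 ± 0.18 and 0.67 ± 0.18. They lost their call without chow wild type 2 (adjusted p = 0.0609, 0.0743 and 0.065), and Fga also without chow wild type 3 (0.0519). The cholangiocyte marker Krt19 rose by 1.16 ± 0.41. It lost its call, at log2 values of 0.95 to 1.22, without chow wild type 1 or 3 (0.144 and 0.0909), high-fat wild type 2, 3 or 4 (0.0543, 0.0904 and 0.0827) or both libraries (0.0775). Muc1, an epithelial mucin gene, rose by 1.60 ± 0.53. Its call was lost, at 1.12 to 1.62, without chow wild type 1 or 3 (0.108 and 0.0991), high-fat wild type 2 (0.125) or both libraries (0.089), with voom (0.0721) and in a fit of only those groups (0.0686). The granzyme gene Gzma rose by 2.86 ± 0.83 and lost its call, at 2.37 and 2.38, without chow wild type 3 (0.060) or both libraries (0.0587). The lymphocyte receptor gene Il7r rose by 1.80 ± 0.54. It lost its call, at 1.47 to 1.63, without chow wild type 2 or 3 (0.086 and 0.0809), high-fat wild type 2 (0.051) or both libraries (0.0837). The red cell anion exchanger gene Slc4a1 rose by 2.26 ± 0.68. Its call was lost, at 1.77 to 2.10, without chow wild type 1 or 3 (0.0836 and 0.0702), high-fat wild type 2 (0.059) or both libraries (0.0516). Of the 94 genes that the naming rule took and that passed in wild type, 13 lost their call without 1 library and 0 changed sign.

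**Figure D3:**
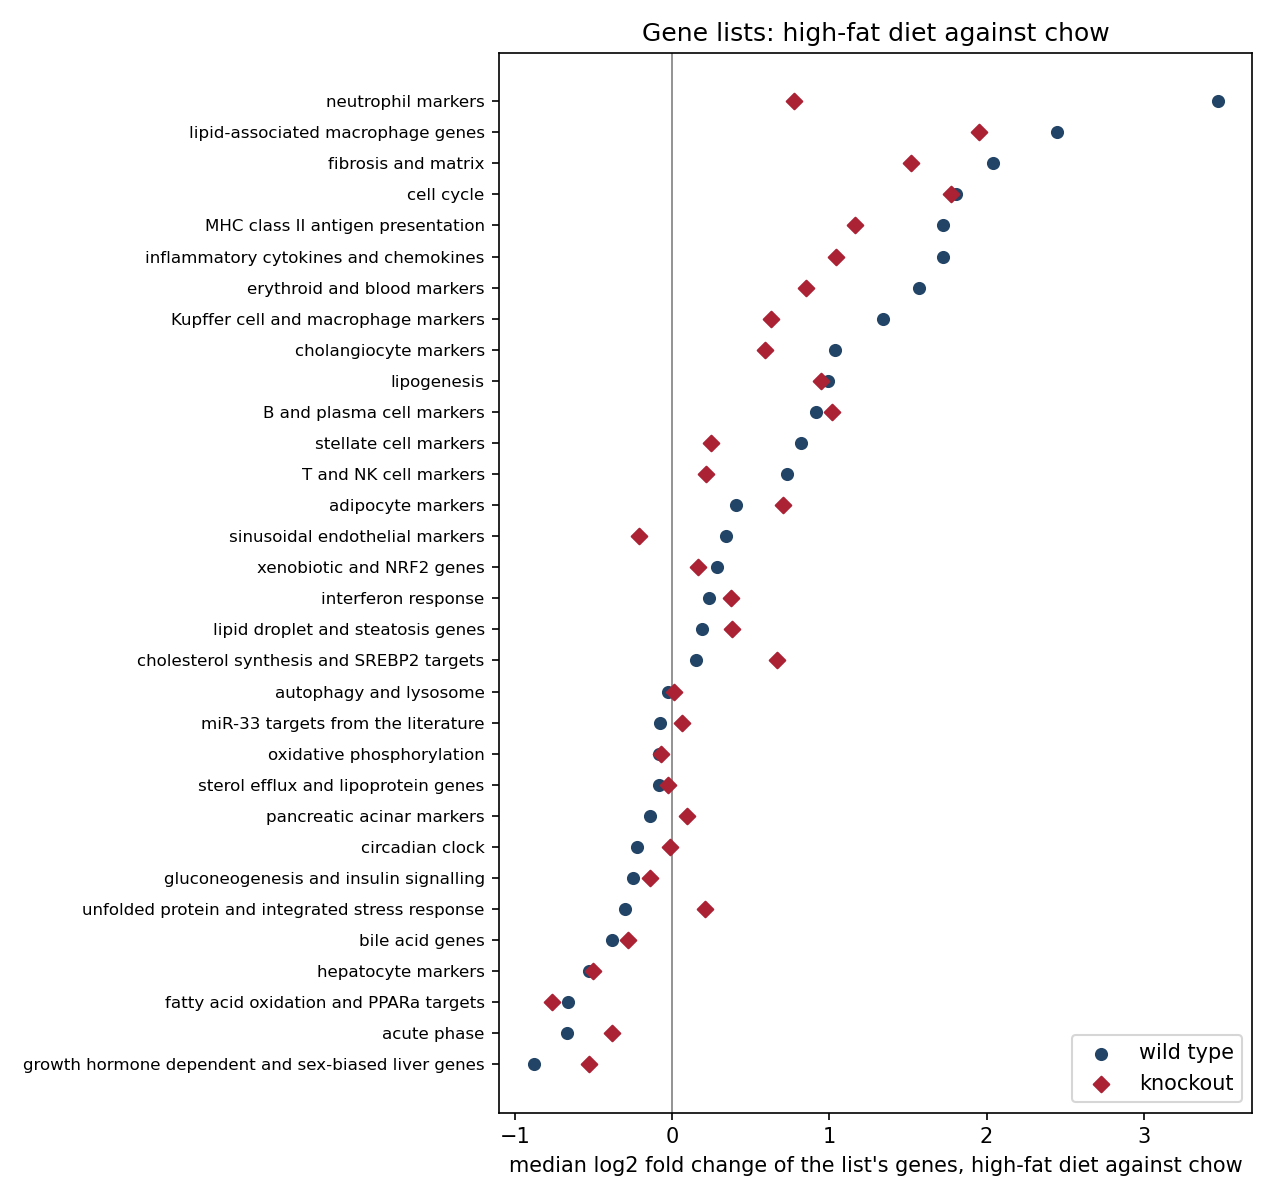
Median log2 fold change of each of the 32 gene lists for high-fat diet against chow (horizontal axis), in wild type (circles) and knockout (diamonds). Fibrosis and matrix genes had medians of 2.04 and 1.52, and fatty acid oxidation genes had -0.66 and -0.77. The neutrophil median in wild type was 3.47, and 2.25 with Mmp8, at 0 in chow wild type, at its bound, and it was 2.14 and 2.01 without high-fat wild type 2 and 4.

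High-fat diet against chow in knockout changed 5650 genes, 2922 higher and 2728 lower. Of these, 1755 changed at least 2-fold, 1220 higher and 535 lower. The share of CT010467.1 differed between these groups, at 13.6 ± 1.52% (SD) on chow and 5.91 ± 5.77% on high-fat diet. With the ribosomal RNA covariate 3847 genes changed, 2087 higher and 1760 lower. Mmp12 rose by 5.19 ± 0.21 and Gpnmb by 5.43 ± 0.39. The fatty acid omega-hydroxylase genes Cyp4a14 and Cyp4a10 fell from 6249 ± 1540 to 327 ± 155 CPM and from 3418 ± 1213 to 217 ± 54.1 CPM. Fibrosis genes rose in 30 of 34 over all genes and 31 adjusted over the list alone and fell in 1 by both counts, with a median of 1.52. Fatty acid oxidation genes fell in 26 of 32 over all genes and 27 adjusted over the list alone. Both lists, the inflammatory list and the lipid-associated macrophage list kept an adjusted p = 0.026 with an estimated correlation. Kupffer cell markers rose in 7 of 16 over all genes and 8 adjusted over the list alone and fell in 1 by both counts, and stellate cell markers rose in 6 of 15 and fell in 3 by both counts (adjusted p = 0.715 and 0.832 with an estimated correlation). Erythroid markers rose in 1 of 8 by both counts, and neutrophil markers in 1 of 6 over all genes and 0 adjusted over the list alone (adjusted p = 0.715 and 0.816 with an estimated correlation). Adipocyte markers rose in 3 of 6, B and plasma cell markers in 2 of 10 and T and NK cell markers in 0 of 14, each by both counts, and cholangiocyte markers in 1 of 10 over all genes and 0 adjusted over the list alone (adjusted p = 0.169, 0.715, 0.87 and 0.715 with an estimated correlation). Hepatocyte markers fell in 9 of 16 over all genes and 12 adjusted over the list alone (adjusted p = 0.201 with an estimated correlation). Endothelial markers fell in 5 of 15 by both counts (over all genes and adjusted over the list alone), including Stab2 by 0.74 ± 0.13, and 7 rose in wild type (adjusted p = 0.715 in knockout and 0.502 in wild type with an estimated correlation). Cholesterol synthesis genes rose in 14 of 27 over all genes and 16 adjusted over the list alone and 2 fell by both counts, with Sc5d, a late enzyme of the pathway, rising by 0.99 ± 0.16 and Tm7sf2 falling by 1.35 ± 0.11 (adjusted p = 0.715 with an estimated correlation). Lipogenesis genes rose in 15 of 22 over all genes and 18 adjusted over the list alone and fell in 1 by both counts, with the lipogenic regulator Srebf1 at 2.43 ± 0.25 (adjusted p = 0.173 with an estimated correlation).

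In knockout, the metallothionein gene Mt1 fell by 1.38 ± 0.38 and lost its call without chow knockout 4 (log2 -0.82, adjusted p = 0.051) and with the ribosomal RNA covariate (0.0713). The heme-binding protein gene Hpx rose by 0.45 ± 0.16. Its call was lost, at log2 values of 0.36 to 0.48, without chow knockout 1, 2 or 3 (0.135, 0.0626 and 0.128), high-fat knockout 3, 4 or 5 (0.066, 0.101 and 0.0679), with no filter (0.0552) and with the covariate (0.187). Krt19 rose by 1.07 ± 0.39. It lost its call, at 0.77 to 1.08, without chow knockout 1, 3 or 4 (0.0791, 0.0977 and 0.0864), high-fat knockout 2, 3 or 5 (0.0679, 0.0761 and 0.0874), in a fit of only those groups (0.0664) and with the covariate (0.234). The B cell coactivator gene Pou2af1 rose by 1.36 ± 0.44. Its call was lost, at 1.11 to 1.35, without chow knockout 1, 2 or 4 (0.0793, 0.0536 and 0.0732) or both libraries (0.0568). The neutrophil collagenase gene Mmp8 rose by 1.95 ± 0.72, from a mean of 0.0434 CPM. It lost its call, at 1.60 to 2.08, without chow knockout 1 or 3 (0.119 and 0.0979), with no filter (0.0567), in the DESeq2 Wald test (0.0619) and with the covariate (0.151). Of the 93 genes that the naming rule took and that passed in knockout, 5 lost their call without 1 library and 0 changed sign.

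The diet effects in the genotypes had r = 0.816 and rho = 0.765 across genes. Of 2564 genes higher in wild type, 1888 were also higher in knockout, where independent lists would share 445. Of 2382 lower genes, 1725 were also lower, where independent lists would share 386. Opposite calls numbered 1 in each direction. The knockout effect on high-fat diet and the diet effect in wild type share the high-fat wild-type libraries. Their r was -0.396, against -0.480 in simulated unchanged groups, and their covariance was -0.0719 against -0.0369 simulated. The simulation held no diet effect, while the real diet effect widens the spread across genes. The observed and simulated r can therefore not be compared directly. With the high-fat wild-type libraries split between the comparisons, r averaged -0.172 over 6 splits, from -0.317 to 0.017.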

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

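The tests of histone copies, dividing cells, placement on chromosome 13 and ribosomal reads at Lars2, the fit without the libraries that stood apart and the ribosomal RNA covariate (also for the Lars2 diet change) were chosen after the results were seen, while those of the chromosome 13 segment and of reassigned genotypes were set before their own values were seen, for patterns already noticed.

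Hist1h2br, Hist1h2bq and Hist1h2bk were higher in knockout livers on both diets. The cell cycle list had a median of 0.15 for the mean of both diets, which argues against more dividing cells. The knockout effects of other genes at the chromosome 13 segment correlated at the 45.4 percentile of runs elsewhere, but the 20 genes with the smallest p were left out, 7 of them in the segment, so this excludes nothing and a segment difference stays open. Of the 10 genes with the smallest p, 6 lay on chromosome 13, against 0.405 expected for independent genes. Of 100 regroupings 1 reached that number, the real one, with 3 in the highest other. Chromosome 13 was chosen because these genes lie there, and other chromosomes were not counted in the regroupings. The 6 also include the 3 H2B genes, which may share reads. The others were CT009713.5 (log2 1.88 ± 0.38 for the mean of both diets), Hfe (-0.25 ± 0.05) and Rnf44 (0.31 ± 0.07). They are not H2B genes and did not pass over all genes, and reads shared between H2B genes do not account for them. Since the chromosome was chosen after these genes were seen, chance placement is not excluded. Reads moved between copies cannot be told apart from a real rise, since the fall of the other 7 H2B genes as a share of the rise of the 3 was 1.26 ± 1.32 on high-fat diet and 3.65 ± 2.05 on chow, spreads too wide to decide.

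Endothelial, fibrosis and macrophage lists had opposite signs with the knockout on the diets, but the Kupffer cell median on high-fat diet was 0.03 without high-fat wild type 2, against -0.16. The fibrosis median on chow was 0.27, with 29 of 34 above 0, and was 0.15 without chow wild type 3. Lipid-associated macrophage genes had a median of -0.29 on high-fat diet, with 16 of 16 below 0, and -0.16 without high-fat wild type 4. On chow their median was 0.08, with 9 of 16 above 0. The median difference of the endothelial list was -0.67, stayed at -0.59 without high-fat knockout 1 and chow wild type 3, and was -0.70 with the ribosomal RNA covariate, which argues against either as the whole cause. Over all 4410 reassignments of genotype within diet, its score had an exact two-sided p of 0.00113, adjusted to 0.0363 over the 32 lists. Fibrosis (0.0118, adjusted 0.184), neutrophil (0.0172, adjusted 0.184), inflammatory (0.0265, adjusted 0.212) and Kupffer cell lists (0.0578, adjusted 0.37) failed the correction. The reassignments ask whether genotype matters on either diet, and the pattern had been noticed in these same data. By camera with an estimated correlation, the endothelial list had an adjusted p of 0.0538 for the difference. Chance differences between libraries therefore stay open for the endothelial list as well as for the others. An opposite effect of the knockout on endothelial genes by diet may be a hypothesis, and differing shares of cell types between livers stay open as untested.

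Lars2, named after its values were seen, followed the ribosomal RNA gene CT010467.1 across the 16 libraries after group means were removed. It had r = 0.985 and rho = 0.95 (permutation p = 2e-05 for r), and r = 0.992 without the 2 libraries farthest from the median. Ribosomal RNA reads counted at Lars2 may be a source of its values. Its diet change in wild type was -0.86 ± 1.01 and was -0.48 ± 0.19 with the covariate (adjusted p = 0.0614), so the test could not decide whether a diet change remains.

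A library lay far from its group in 25 of the 276 groups of values tested, against about 13.8 by chance, and 11 of these were high-fat knockout 1. Chow wild type, with 3 libraries, was too small for this test and was left out. Its replicate 3 had a CT010467.1 share of 2.54%, against 11.3% and 13.3% in replicates 1 and 2. The acute phase score of that replicate was 9.14, against 7.46 and 7.72. The genes among these values are the ones named here, some of them added after such values had been seen, and values of the same library are not independent, so 13.8 is only a guide. The number given for each is its gap to the nearest library as a share of the group's range. High-fat knockout 1 was highest for Hsd3b5 (0.994), Mup12 (0.893), Mup14 (0.949), Mup15 (0.935) and Serpina1e (0.964), lowest for Col3a1 (0.75), highest in the Kupffer cell (0.729) and endothelial (0.726) scores, and lowest in the fatty acid oxidation (0.898), lipid droplet (0.828) and oxidative phosphorylation (0.831) scores. Among chow knockout libraries, replicate 3 was lowest in the share of CT010467.1 (0.844), in its CPM (0.834) and for Hmox1 (0.884), and highest for Gzma (0.908) and Thrsp (0.854). Chow knockout 4 was highest for Mt1 (0.857) and the adipocyte score (0.847) and lowest for Wee1 (0.839), chow knockout 1 was highest for Sprr1a (1, at 0.0543 CPM against 0), and chow knockout 2 was lowest in the sterol efflux score (0.872). High-fat wild type 1 was highest for Cyp4a14 (0.85), replicate 2 for Mki67 (0.864) and the Kupffer cell score (0.881), and replicate 4 was lowest in the fatty acid oxidation score (0.854).

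Knockout effects on the diets differed by camera at the preset correlation for 15 lists, and for 0 with an estimated correlation. The median differences were 0.47 for cholesterol synthesis, -0.054 for fatty acid oxidation, -0.56 for fibrosis, -0.43 for inflammatory, -0.47 for lipid-associated macrophage, -0.74 for Kupffer cell, -0.67 for endothelial and -0.33 for stellate cell genes. They were -0.53 for T and NK cell, -2.61 for neutrophil (-1.77 with the chow effect of Mmp8 set to 0), -0.63 for erythroid, 0.30 for unfolded protein response, 0.20 for circadian clock, 0.22 for interferon and -0.39 for MHC class II genes. Several moved by over 1.5 times with 1 library left out. Leaving out chow wild type 1 gave -1.12 for Kupffer cell, -1.10 for T and NK cell, -0.78 for inflammatory, -0.995 for MHC class II and 0.04 for clock genes. Leaving out chow wild type 2 gave -0.33 for T and NK cell, -0.27 for inflammatory, -0.14 for fatty acid oxidation and 0.33 for clock genes, and chow wild type 3 -0.28 for lipid-associated macrophage, -0.14 for MHC class II and 0.09 for clock genes. Among chow knockouts, replicate 1 gave -1.73 for neutrophil and 0.14 for interferon genes, replicate 2 gave 0.12 for interferon and 0.09 for clock genes, replicate 3 gave -0.08 for fatty acid oxidation, and replicate 4 gave -1.42 for neutrophil, -0.17 for lipid-associated macrophage, -0.09 for fatty acid oxidation and 0.36 for interferon genes. Among high-fat wild types, replicate 1 gave 0.11 for clock genes, replicate 2 gave -1.72 for neutrophil, -0.34 for erythroid, -0.33 for T and NK cell and -0.22 for lipid-associated macrophage genes, and replicate 4 gave -1.59 for neutrophil, -0.26 for MHC class II and -0.09 for fatty acid oxidation genes. Among high-fat knockouts, replicate 2 gave -0.23 for MHC class II, replicate 3 gave -0.89 for T and NK cell and 0.30 for cholesterol synthesis, and replicate 4 gave -1.10 for erythroid genes, while fatty acid oxidation gave -0.01, -0.09, -0.08 and -0.08 without replicates 1, 3, 4 and 5.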

How the results depend on the processing

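The ribosomal RNA covariate and the fit without high-fat knockout 1 and chow wild type 3 were chosen after seeing the data. No paired analysis was possible because replicate numbers follow accession order only. Pseudocount alternatives apply to FPKM and were not run. The genes passing with knockout on high-fat diet numbered 3 without a filter, 0 with the stricter filter, 8 with the DESeq2 Wald test, 2 with voom and 4 in a fit of only those groups. On chow they numbered 0 with the stricter filter, 2 with DESeq2, 0 with voom, 0 in a fit of only those groups and 2 with the covariate, and 0 to 3 with 1 library left out. For the difference between diets they numbered 13 with DESeq2, 1 with the covariate and 0 to 4 with 1 library left out. For the mean of both diets they numbered 0 with the stricter filter, 5 with DESeq2, 1 with voom and 2 to 5 with 1 library left out. The stricter filter removes the histone genes. Gene lists passing with an estimated correlation numbered 0 for knockout on high-fat diet, 0 on chow, 3 for diet in wild type, 4 for diet in knockout, 0 for the difference and 0 for the mean. At the preset correlation 13 lists passed on chow and 12 for the mean. At that correlation 5 and 3 passed without those 2 libraries, and 6 to 13 and 2 to 13 with 1 library left out, the lowest without chow wild type 3 in both, and for the mean 4 without chow wild type 2 and 7 without high-fat knockout 1. The mean difference of genes with an 8mer site was 0.0185 (95% range -0.00891 to 0.0448) on high-fat diet and -0.00658 (-0.0438 to 0.0296) on chow, so both ranges include 0. These ranges leave out the spread between site genes and between libraries. The per-library difference for 8mer genes had an exact p of 0.246 on high-fat diet and 0.486 on chow. The r of the knockout effects was -0.168 under the stricter filter. With the high-fat wild-type libraries split, the r of knockout and diet effects was -0.166, -0.165, -0.168, -0.317 and -0.235, and turned to 0.017 with replicates 1 and 3 in the knockout contrast, with a mean of -0.172 over the 6 splits. The median of acute phase genes on chow turned to 0.0394 without those 2 libraries and ran from -0.608 to 0.0435 with 1 library left out, and that of B and plasma cell markers on high-fat diet ran from -0.0308 to 0.719. Without those 2 libraries the camera direction of fatty acid oxidation genes for the difference turned, at a median of -0.00592. The cause was not tested for these. Totals of genes changed by diet stayed within 1.5 times under every alternative run, while the lower genes in knockout were 1760 with the covariate against 2728.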

Other observations

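The tests of the seed 7-mer and of the regroupings were chosen after the results were seen. Genes of MHC class II antigen presentation rose on high-fat diet in 10 of 10 wild-type members by both counts, and in 9 of 10 in knockout, also by both counts (over all genes and adjusted over the list alone), with the protease gene Ctss at 1.86 ± 0.19 and 1.14 ± 0.16. Their adjusted p = 0.194 and 0.406 with an estimated correlation. The heme oxygenase gene Hmox1 rose by 1.64 ± 0.16 in wild type. Among circadian genes, Clock fell by 0.78 ± 0.10 in wild type and 0.91 ± 0.09 in knockout, while Wee1 rose by 1.16 ± 0.20 and 1.46 ± 0.17.

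A hypothesis was that genes carrying the miR-33-5p seed site rise in the knockout. Among all 7-mers, the seed matches 7mer-m8 and 7mer-A1 ranked 48.35% and 42.92% from the top for the mean of both diets. They ranked 66.37% and 29.32% on high-fat diet and 30.51% and 54.1% on chow, so neither lay near the top. The test covers all genes with a match, and a rise of fewer genes stays open.

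Other splits of the libraries were refitted for each count of genes. On high-fat diet 6 of 100 splits gave as many genes for the knockout as the real 1, with up to 40 in another split, so chance is not excluded for the count. A count of 40, several times the real 1, points to a structure of the samples whose source was not tested. On chow 7 of 35 splits did, with up to 3 in another, so chance is not excluded for that count. The counts take any gene and do not test Hist1h2br itself. Hist1h2br lay between 2.64 and 4.61 CPM in knockout libraries and between 0.168 and 0.988 CPM in wild-type libraries. For the difference between diets edgeR called 0 genes (1110 at an unadjusted p under 0.05, 13 by the DESeq2 Wald test, 0 by voom). Each of the 100 splits reaches 0, so the count of 100 decides nothing, and the highest other was 8. For the mean of both diets 2 of 100 splits gave at least the real 3, the real one among them, with 4 in another. The 3 are near-identical H2B genes whose reads may have been divided between copies. The count may thus not stand for 3 separate changes, and chance is not excluded for it. By genes at an unadjusted p under 0.05 the knockout comparisons did not stand out, since 82 of 100 splits reached the real 586 for the mean, 55 of 100 the real 641 on high-fat diet, 11 of 35 the real 1001 on chow and 22 of 100 the real 1110 for the difference. Of the genes tested, 3.48% for the mean and 3.81% on high-fat diet had such a p, below the 5% that chance gives for independent genes. For diet in wild type the real split alone of 35 reached 4946, with 2324 the highest other, and in knockout the real split alone of 100 reached 5650, with 3665 the highest other. Shares of 1 of 35 and 1 of 100 were the smallest these tests could give, so a chance split is unlikely for both but not excluded. A real split that stands out also does not separate diet from the number series in the titles.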
